A study of Mus musculus with 2 samples.

How the data were processed

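Total RNA longer than 200 nucleotides, from the liver of adult C57BL/6J mice aged 8 weeks, was sequenced in 2 libraries. The labels number them as biological replicates 1 and 2 and give no other condition, so both form 1 group. The labels give a separate biosample for each library but the same donor identifier for both, do not give the sex of the animals and do not say whether the samples came from separate animals. The spread between the libraries, the SDs and the coefficient of variation may therefore be partly or wholly technical.

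The authors quantified each library separately against the mm10 assembly and the GENCODE M4 gene models, per the notes deposited with each library. Transfer RNA models and spike-in sequences were appended to the gene models, as the row names show. The aligner and the quantifier are not given in the sources used here; the column names are those that RSEM writes. The expected count of a gene is an estimated, unnormalised number of fragments per the file headers, and it need not be whole because reads that match several genes are divided among them. The deposited TPM values are length-scaled abundances (TPM) over all features of the file, spike-ins included. FPKM values, per the file headers, are scaled to length and library size, and were used only as an alternative threshold for detection. The transcript table gives the deposited share of each transcript in its gene as a percent. The deposited signal columns that bound the interval of each TPM and FPKM estimate were not used. The posterior standard deviation of each count, per the file headers, was used as a measure of how far shared reads leave a count uncertain; counts with an SD under 1% were taken as little affected.

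The gene table held 69691 rows per library. Of the 43346 mouse gene identifiers, 42462 matched the GENCODE M21 annotation of the same assembly, which supplied symbols, classes and coordinates, and 884 did not. The 26248 transfer RNA rows held no counts, and 97 rows were spike-ins or the phiX control. Listed genes with no matching symbol were not analysed here. The TPM values were rescaled to the same total without spike-ins and are called endogenous TPM. TPM divides by the length left after the fragment length is taken off, so RNAs close to the fragment length receive large values from few counts. The U1 gene Rnu1a1 had an effective length of 1.49 nucleotides in replicate 1 and 2.21 in replicate 2. Annotated minus effective length in long genes gave mean fragment lengths of 212 and 202 nucleotides.

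Expected counts were rounded to whole numbers for edgeR 4.0.16 and DESeq2 1.42.0 in R 4.3.3. TMM factors were 0.950 for replicate 1 and 1.05 for replicate 2. The biological coefficient of variation was the square root of the edgeR common dispersion in an intercept-only design after filterByExpr. Ratios between the libraries are replicate 2 over replicate 1, as log2 of TMM-scaled CPM, which is counts scaled to the library total, plus 0.5. They understate the change of low genes, since the pseudocount equals 39.8 counts in replicate 1 and 37.4 in replicate 2. Genes entered the count of 2-fold differences with a mean endogenous TPM of 1 or more and a mean expected count of 10 or more. A comparison of single libraries has no replicate check, and no p-value across genes is given. Other values were computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

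Of the gene lists and cell type lists, 49 in all, each was fixed before the data were examined, as were the comparisons, the alternatives not named as later choices and the rule for naming genes. The shift of a list is the median ratio of its members with a mean endogenous TPM of 1 or more. It was set against 10000 random lists of the same size, matched on mean expression in 20 bins, and was computed for the 37 lists with 3 or more such members. The rule for naming genes takes the 20 genes of highest mean TPM and the 3 highest members of each list, of which examples are given; some genes that the rule takes are left out because they are withheld for evaluation. It also takes any member of the sex chromosome, sex-biased, clock and immediate early lists, and the 5 highest long noncoding genes. By ratio, it takes the 10 genes highest in each library. These need a mean count of 100 or more and a mean endogenous TPM of 1 or more. The rule calls the values of single Mup, Serpina1, hemoglobin and cytochrome P450 genes uncertain because these families hold near-identical copies. The posterior SD left many of them, such as Cyp3a16, Cyp3a11 and Serpina1a, little affected, but was a large part of the count for the copies of 7SL RNA, most U1 copies named, Gm24497, Amy2a5, Amy2a2 and, in replicate 2, Cyp3a41b.

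The coefficient of variation and the count of 2-fold differences were tested on simulated counts, and the other steps were not. With a simulated coefficient of variation of 0.2 over 15077 genes, 0.199 was recovered. For the count of 2-fold differences, counts were drawn with Poisson noise alone and 200 genes were changed 4-fold. All of the 123 that entered the step (100%) were called, and 0 unchanged genes were called among the 7702 in the step. Without spread beyond counting noise, this checks the calculation only. It does not show how many unchanged genes would pass 2-fold between real libraries. The alternatives covered the scaling, the pseudocount, the filters on low values, the unit and each replicate left out. For the ratio of deposited TPM, 0.01 was added, the resolution of the files. Rescaling TPM over protein-coding genes, counting protein-coding genes alone, and a correction for GC content and length in 10 bins each were chosen after seeing the data.

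The total of expected counts was 84831830 in replicate 1 and 71832859 in replicate 2. A count of 0 allows up to 0.0358 CPM in replicate 1 and 0.0422 CPM in replicate 2 (3 counts of the endogenous total). These floors cover counting error only. The interval for the share of genes with the same dominant transcript treats genes as independent draws.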

Results

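Total RNA of adult mouse liver was profiled in 2 biological replicates that form a single group. Endogenous genes took 83816487 expected counts in replicate 1 and 71068191 in replicate 2. With 1 group, the design asks which RNAs liver holds, at what level, and how far the replicates lie apart. Levels are endogenous TPM given as mean ± SD over both libraries unless a replicate is named. The bulk of genes had higher TPM in replicate 2, with a median log2 ratio of deposited TPM of 0.51. An SD of TPM includes this offset and does not rank genes by how well the libraries agree. Under TMM, Serpina3k, with an SD of 3.46 TPM, had a log2 ratio of -0.55, and Alb, with an SD of 2865 TPM, 0.11.

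By endogenous TPM, the most abundant RNAs measured were the structural RNAs of ribonucleoprotein particles. Rn7s1 and Rn7s2, which encode the 7SL RNA of the signal recognition particle, together held 68.2% ± 3.38 of endogenous TPM (SD, n = 2) and 21.04% ± 3.69 of expected counts. Rn7s2 (ENSMUSG00000099250.1) lies on chromosome 12 from 69361182 to 69361481, and Rn7s1 (ENSMUSG00000099021.1) on the same chromosome from 69159295 to 69159594 (mm10). Rn7sk, the 7SK RNA that holds the elongation factor P-TEFb, stood at 52543 ± 15409 TPM. Rpph1, the RNA of ribonuclease P, reached 36092 ± 1150 TPM and Rmrp, the RNA of ribonuclease MRP, 16251 ± 2969 TPM. The order below 7SL depends on the unit. By expected counts, all annotated ribozymes, Rpph1 and Rmrp among them, took 1.68%. The albumin gene Alb alone had 4028016 of 83816487 counts in replicate 1 and 4087840 of 71068191 in replicate 2. Members of the list of abundant small structural RNAs summed to 79.0% ± 1.35 of TPM, and the 10 most abundant genes to 82.0% ± 1.11.

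U1 small nuclear RNA copies filled much of the rest of the top 20, at levels their short effective lengths inflate. Gm22513 stood at 8149 ± 2596 TPM from 4676 and 2805 counts. Gm25679, Gm22634 and Gm22068 stood between 5344 and 5357 TPM. Gm26444, Gm23849, Gm22317, Rnu1a1 and Gm23804 were also among the 20. Rnu1a1 had 2183 counts in replicate 1 and 498 in replicate 2, a log2 ratio of -1.96.

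Among nuclear messenger RNAs, Alb, which encodes serum albumin, was the most abundant at 9004 ± 2865 TPM. Alb (ENSMUSG00000029368.9) lies on chromosome 5 from 90460897 to 90476602. Apoe, a lipoprotein component, followed at 3112 ± 554 TPM and Trf, the iron carrier transferrin, at 2780 ± 1068 TPM. The mitochondrially encoded mt-Co1 and mt-Co3, subunits of cytochrome c oxidase, reached 3330 ± 633 and 2978 ± 639 TPM. The value of mt-Atp8, 3804 ± 1098 TPM, comes from a short gene. By expected counts, which are not divided by length, the 10 most abundant genes held 35.8% ± 2.53, and over protein-coding genes alone 19.1% ± 0.463 of TPM.

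Protein-coding genes took 70.0% ± 3.59 of expected counts and 13.01% ± 2.90 of endogenous TPM. The annotated class misc_RNA, which holds the 7SL and 7SK genes, took 23.2% ± 3.37 of counts and 73.4% ± 1.84 of TPM. Mitochondrially encoded genes held 2.92% ± 0.158 of counts, ribozymes 1.68% ± 0.112, long noncoding genes 1.21% ± 0.0240 and pseudogenes 0.722% ± 0.00368. Annotated ribosomal RNA genes and transfer RNA rows had 0 counts in both libraries. The listed ribosomal RNA symbols Rn45s and Rn18s had no match, so these zeros do not measure the ribosomal RNA content of the libraries.

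**Figure D1:**
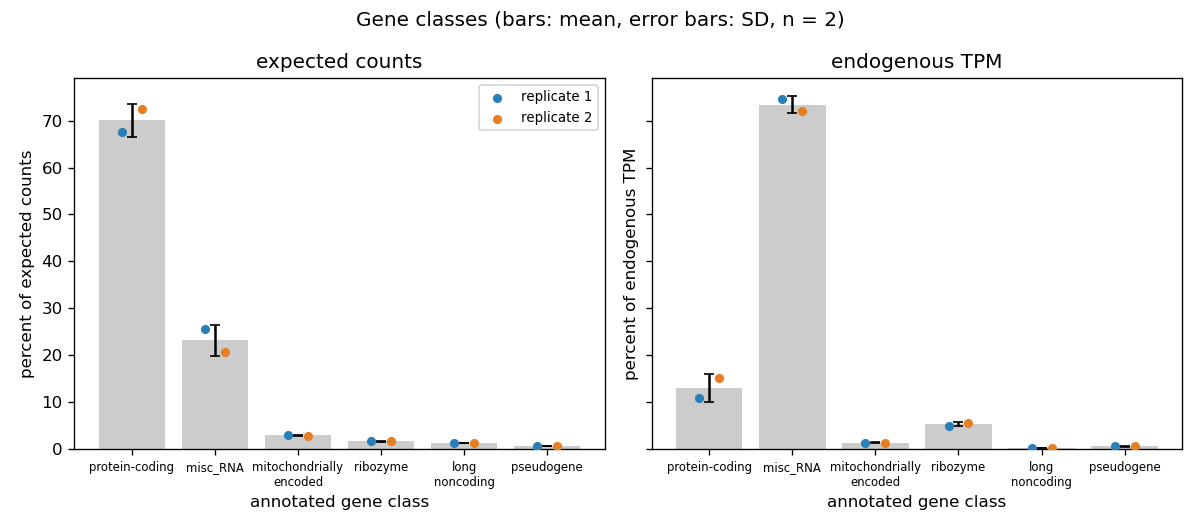
Percent of expected counts (left) and of endogenous TPM (right) by annotated gene class; bars are means, error bars SD (n = 2) and points the libraries. Protein-coding genes hold 70.0% of counts and 13.01% of TPM.

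In both libraries, 6945 genes reached 1 TPM, of which 6651 were protein-coding, 121 pseudogenes and 70 long noncoding. Replicate 1 alone gave 7034 genes and replicate 2 alone 8240. With TPM rescaled over protein-coding genes, a choice made after seeing the data, 11135 genes passed. Of the genes that the annotation classes as long noncoding, the highest were Malat1, a nuclear RNA, at 764 ± 16.3 TPM and Gm26917 at 365 ± 155 TPM. Gm10076, Gm28967 and Gm42418 followed at 91.2 ± 6.06, 77.8 ± 7.89 and 41.4 ± 3.08 TPM.

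Among the fixed lists of nuclear protein-coding genes, secreted proteins held the largest share. Plasma carrier and secreted proteins summed to 1.91% ± 0.578 of endogenous TPM, with all 20 members at 1 TPM or more in both libraries, and held 14.6% ± 1.20 of protein-coding TPM. Ahsg, which encodes fetuin A, stood at 1439 ± 440 TPM. Apolipoproteins and lipoprotein handling genes took 0.918% ± 0.192, led by Apoe, Apoa2 at 2138 ± 217 TPM and Apoc1 at 958 ± 146 TPM. Serine protease inhibitors took 0.687% ± 0.204, with Serpina3k at 1580 ± 3.46 TPM and the paralogs Serpina1b and Serpina1a at 1254 ± 290 and 1007 ± 423 TPM. Coagulation factors held 0.273% ± 0.0634, with fibrinogen chains Fgg at 527 ± 71.9 TPM and Fga at 434 ± 102 TPM and antithrombin (Serpinc1) at 495 ± 194 TPM. Complement proteins held 0.193% ± 0.0549, led by C3 at 870 ± 404 TPM, Cfb at 197 ± 34.8 TPM and Mbl2 at 126 ± 2.16 TPM.

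Cytosolic ribosomal proteins held 0.549% ± 0.155 of TPM, and the lists of metabolic enzymes each held less. Cytochrome P450 enzymes summed to 0.432% ± 0.0719 of TPM, with 45 of 80 members detected in both libraries. The highest were Cyp3a11 at 1132 ± 675 TPM, Cyp2e1 at 429 ± 12.8 TPM and Cyp2c29 at 227 ± 86.6 TPM. Amino acid catabolism genes held 0.339% ± 0.0738, with Gnmt at 508 ± 182, Hpd at 472 ± 102 and Bhmt at 405 ± 113 TPM. Conjugating and detoxifying enzymes held 0.320% ± 0.0548, led by the carboxylesterase Ces1c at 534 ± 100 TPM, Adh1 at 388 ± 27.8 TPM and Gsta3 at 264 ± 16.6 TPM. Urea cycle genes held 0.188% ± 0.0543, with Cps1, the first enzyme of the cycle, at 503 ± 148 TPM, Ass1 at 496 ± 226 TPM and Arg1 at 289 ± 55.4 TPM. Fatty acid oxidation and PPAR alpha targets held 0.160% ± 0.0210, with Fabp1 at 908 ± 339 TPM. Gluconeogenesis and glycogen metabolism held 0.143% ± 0.0291, with Pck1 at 321 ± 70.2 and Fbp1 at 221 ± 88.8 TPM. Bile acid genes held 0.119% ± 0.00612, led by Slc27a5 at 205 ± 39.2 and Akr1c6 at 175 ± 7.44 TPM. Lipid synthesis lists were lower, at 0.0747% ± 0.0231 for fatty acids and triglycerides, where Scd1 stood at 279 ± 191 TPM, and 0.0486% ± 0.00914 for cholesterol, where Sc5d stood at 93.7 ± 18.7 TPM.

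Hepatocyte markers summed to 1.52% ± 0.458 of TPM and far exceeded every other cell type list. Erythroid genes took 0.0199% ± 0.00923, mainly the globins Hbb-bs at 107 ± 49.9 TPM and Hba-a2 at 42.4 ± 22.5 TPM. Pancreatic acinar markers took 0.0136% ± 0.0111, at 0.0215% in replicate 1 and 0.00571% in replicate 2. Kupffer cell or macrophage markers took 0.0104% ± 0.00103, with Cd5l at 18.98 ± 1.85 and Clec4f at 18.2 ± 0.866 TPM. Hepatic stellate cell markers took 0.00729% ± 0.00240, led by Dcn at 22.9 ± 5.47 TPM. Sinusoidal endothelial markers took 0.00716% ± 0.00162, led by Clec4g at 14.8 ± 0.368 and Stab2 at 10.5 ± 3.45 TPM. Cholangiocyte markers were low, with Spp1 at 4.42 ± 0.0871 TPM and 2 of 14 detected in both libraries. B cell markers held 0.000696% ± 0.000715 of TPM and intestinal epithelial markers 0.000991% ± 0.000379. No member of the T or NK cell, neutrophil, smooth muscle, mesothelial, skeletal muscle or kidney tubule lists had 1 TPM in both libraries.

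Pearson's r of log2(TPM + 1) was 0.964 and Spearman's rho 0.942 over 8329 genes, which are not independent replicates. The biological coefficient of variation was 0.237 over 14703 genes. Chi-square over its degrees of freedom was 196 over 15492 genes, which excludes only that the libraries are copies of each other, since any separate preparations would exceed counting noise. Of 7702 genes, 182 lay over 2-fold apart, 121 higher in replicate 1 and 61 higher in replicate 2. Poisson counting noise gave 0 such genes in each of 100 simulated pairs. That outcome was largely set by the pseudocount and the filters, since 7637 of the 7702 genes had a mean count of 100 or more. It is no measure of the spread between separate preparations. Scaling by the spike-in total gave 84 higher in replicate 1 and 152 higher in replicate 2, and the deposited TPM ratio gave 87 and 621. These scalings moved the median log2 ratio of all genes by 0.28 and 0.55, so the ratios below are relative to the bulk of genes.

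**Figure D2:**
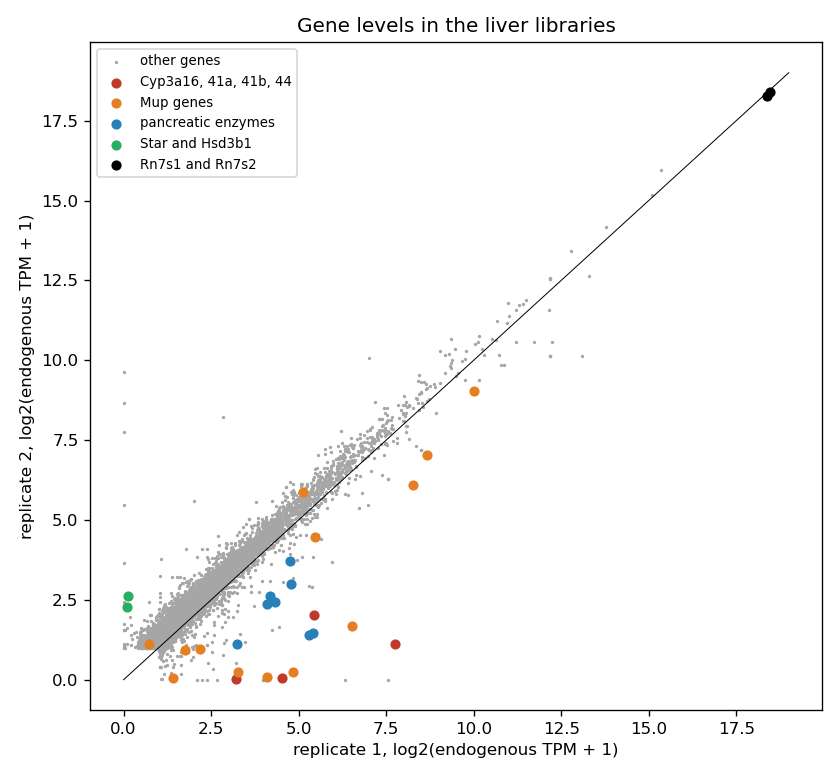
log2(endogenous TPM + 1) of genes with 1 TPM or more in either library, replicate 1 on the x axis and replicate 2 on the y axis; the line marks equal values and colours mark named groups. Pearson's r was 0.964; TPM was not rescaled by TMM, so the bulk lies above the line (median log2 ratio of deposited TPM 0.51), while the 4 coloured Cyp3a genes and the pancreatic enzymes lie below it.

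The genes highest in replicate 1 were cytochrome P450, major urinary protein and amylase genes. Cyp3a41a (chromosome 5, 145694049 to 145720136) had 123726 counts in replicate 1 and 431 in replicate 2, a log2 ratio of -7.96. Its neighbours Cyp3a16, Cyp3a41b and Cyp3a44 had ratios of -7.68, -6.71 and -4.31. The pheromone carriers Mup15, Mup17, Mup19 and Mup16 had ratios of -6.53, -6.22, -5.94 and -4.89. The amylases Amy2a5 and Amy2a2, whose counts shared reads leave uncertain, had ratios of -5.09 and -4.99. The Mup list as a whole had a median ratio of -2.27, with 10 of 11 measured members lower in replicate 2, and Mup3, its highest member, at -1.51.

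Genes highest in replicate 2, by the same filters, were of several kinds. Under a mean of 1 TPM, Cyp11b1 stood above all of them at a log2 ratio of 4.86, and Cyp21a1 stood at 3.98. Hsd3b1, a steroid dehydrogenase, had 33 and 1684 counts, a log2 ratio of 4.65, and Star, which moves cholesterol into mitochondria for steroid synthesis, had 48 and 2021 counts, a ratio of 4.64. Csad, an enzyme of taurine synthesis, had a ratio of 3.39, the glutathione transferase Gsta1 2.71 and the protease inhibitor Serpina1e 2.52. The immunoglobulin genes Igha and Igkc had ratios of 2.60 and 1.78. Gm24497, whose counts shared reads leave uncertain, Gm10132 and Mmd2 had ratios of 3.33, 2.02 and 1.80.

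Of 37 lists with enough measured members, 19 had a median ratio outside the central 95% of random lists, where 1.85 would fall if genes varied independently, which genes regulated together do not; 11 were lower in replicate 2 and 8 higher. Some lists share genes. Pancreatic acinar markers had a median of -2.41, with all 15 measured members over 2-fold lower in replicate 2; Cela2a went from 6802 to 1798 counts and Try4 from 4888 to 834. All 10 skeletal muscle markers had fewer counts in replicate 2, below the level for a list shift, with Acta1 at 669 and 1 counts and Ckm at 431 and 4.

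Pericentral and periportal hepatocyte genes lay on opposite sides of equal values. The pericentral list had a median of -0.61, with 14 of 15 members lower in replicate 2, among them Cyp2e1 at -0.49 and Rgn at -0.83; Cyp2c29 stood at 0.25. The periportal list had a median of 0.36, with 14 of 20 members higher in replicate 2, among them Ass1 at 0.42 and Cps1 at 0.05, while Pck1 stood at -0.11. Interferon response genes had a median of -0.55, with all 15 measured members lower, including Bst2 at -0.23. Erythroid genes had a median of 0.49, replication-dependent histones 0.33, with 29 of 40 higher, and cytosolic ribosomal proteins 0.10, with Rplp1 at 0.38. Acute phase reactants had a median of -0.33, with Orm1 at -1.14, Hp at -0.24 and Hamp, which encodes hepcidin, at 1.08. Bile acid, cholesterol synthesis, cytochrome P450 and Kupffer cell lists had medians of -0.33, -0.34, -0.28 and -0.28. Plasma carriers, serine protease inhibitors and amino acid catabolism genes had medians of 0.09, 0.12 and 0.06. The random lists were not matched on GC content. Genes at 1 TPM or more had a median log2 ratio of -0.23 in the lowest of 10 GC bins and 0.16 in the highest. After a correction for GC content and length, the serine protease inhibitor and amino acid catabolism lists lay inside the random range. The other 17 of the 19 lists stayed outside it. By the deposited TPM ratio, the medians of the interferon, acute phase, bile acid, cholesterol synthesis, cytochrome P450, Kupffer cell and female-biased lists were above 0, and under spike-in scaling those of the cytochrome P450 and Kupffer cell lists were; relative to all genes, each kept its direction. At a mean of 10 TPM, the Kupffer cell, acute phase, amino acid catabolism, histone and male-biased lists lay inside the random range, and the interferon and immediate early lists had too few members.

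**Figure D3:**
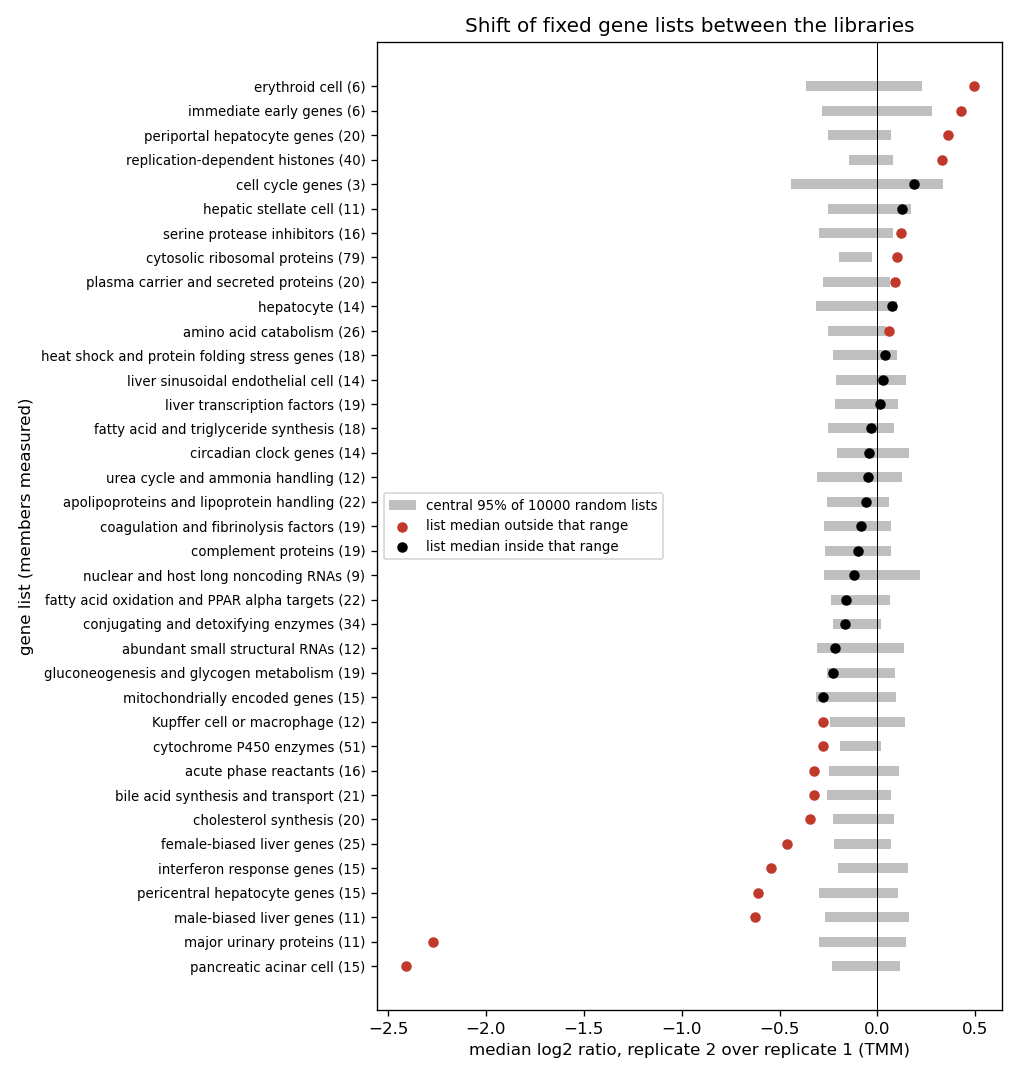
Median log2 ratio (replicate 2 over replicate 1, x axis) of each fixed gene list with 3 or more measured members (y axis); grey bars span the central 95% of 10000 random lists matched on expression, and red points lie outside. The Mup list at -2.27 and the acinar list at -2.41 lie farthest to the left.

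Xist, the RNA of the inactive X chromosome, was present in both libraries at 18.0 and 23.0 TPM, a log2 ratio of -0.078. The 8 Y-linked genes together had 2 counts in replicate 1 and 18 in replicate 2; Kdm5d had 0 and 8, Eif2s3y 0 and 7 and Ddx3y 2 and 3. Uty, Usp9y, Zfy1, Zfy2 and Uba1y had 0 counts in both. Of 25 measured female-biased liver genes, 22 were lower in replicate 2 and the median ratio was -0.46, or -0.94 at a mean of 10 TPM. Besides the Cyp3a genes, Sult2a1, Sult3a1, Sult2a2 and Cyp2b13 had ratios of -3.67, -2.90, -2.25 and -1.88. Cyp2c69, Cyp2a4 and Cyp2b9 stood at -0.19, -0.20 and -0.42, and A1bg at 0.96. Male-biased genes had a median of -0.62 over 11 measured members, or -0.29 and inside the random range at a mean of 10 TPM, with 6 of the 11 lower, among them Hsd3b5 at -2.68 and Cyp2d9 at -1.16, while Gstp1 stood at 0.77.

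Clock genes had a median ratio of -0.04, inside the random range, with Nr1d1 at 1.10 and Ciart at -1.15. Dbp and Tef stood at 12.3 ± 1.15 and 20.7 ± 5.32 TPM, and the activator Arntl at 0.216 ± 0.135 TPM. All 6 measured immediate early genes were higher in replicate 2, with a median of 0.43, among them Junb at 0.53 and Zfp36 at 0.48. Egr1, whose mean lay under 1 TPM, had 137 and 977 counts.

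Transcript shares were compared in 980 protein-coding genes with 10 TPM or more in both libraries. The most abundant transcript held a median of 83.8% ± 0.0283 of its gene. It was the same transcript in both libraries in 940 genes, 95.9% (exact Clopper-Pearson 95% interval 94.5% to 97.1%). That interval treats genes as independent draws, which they are not, and covers no spread between replicates. Transcripts annotated as protein-coding held 87.1% ± 0.253 of the TPM of these genes and retained introns 5.62% ± 0.0135.

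Spike-ins and the phiX control took 1.13% ± 0.0936 of all counts. Across the 75 ERCC spike-ins with reads in either library, Pearson's r of log2(TPM + 1) was 0.997 and Spearman's rho 0.987. The 43 with a mean count of 100 or more had a median log2 ratio of -0.34 under TMM.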

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

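The rescaling over protein-coding genes and the correction for GC content and length were chosen after seeing the data. With a single group there is no test between groups, and leaving out 1 of 2 libraries gives the value of the other, which for a mean lies within 1 SD by construction. Genes detected ranged from 7034 to 8240 with a library left out. No paired analysis was possible because there is 1 group.

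Genes in both libraries numbered 12520 at 0.1 TPM, 14764 at 10 counts and 11135 with TPM rescaled over protein-coding genes. The share of the 10 most abundant genes was 83.1% without mitochondrially encoded genes, 35.8% by expected counts and 19.1% over protein-coding genes. Protein-coding genes took 13.01% of TPM, and spike-ins 0.401% of deposited TPM. Pearson's r was 0.946 with a pseudocount of 0.1, 0.983 without a filter, 0.911 at 10 TPM and 0.975 over protein-coding genes. The coefficient of variation was 0.250 without scaling, 0.295 without a filter and 0.104 as the DESeq2 median gene-wise estimate. The median transcript share was 82.0% at 100 TPM. Genes over 2-fold apart numbered 708 by the deposited TPM ratio and 427 without a filter, where 234 were higher in replicate 1. At a mean of 10 TPM, 12 lists lay outside the random range, of 32 with enough members. Of the 7 lost, the interferon and immediate early lists had under 3 members left, and the medians were -0.31 for Kupffer cell, -0.28 for acute phase, 0.0039 for amino acid catabolism, -0.29 for male-biased and 0.13 for histone genes. The female-biased median was -0.94. The cause was not tested, except that units, filters and gene sets differ by construction.

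Of the 19 lists outside the random range, 7 medians changed sign by the deposited TPM ratio: Kupffer cell 0.26, acute phase 0.19, cytochrome P450 0.21, bile acid 0.21, cholesterol synthesis 0.22, female-biased 0.085 and interferon 0.047. Of the same 19, the Kupffer cell and cytochrome P450 medians changed sign under spike-in scaling, to 0.000653 and 0.00376. Medians of lists inside the range are not counted here. These scalings raised the median ratio over all genes by 0.55 and 0.28, and relative to that median all 19 lists kept their direction. After the GC and length correction, 17 of the 19 stayed outside the random range. The medians of amino acid catabolism, 0.06, and serine protease inhibitors, 0.08, lay inside it, and 4 lists were gained: cell cycle 0.33, fatty acid oxidation -0.16, gluconeogenesis -0.32 and hepatic stellate cell 0.21. The 20 genes named by ratio changed sign under no alternative, which decides little, since they were picked for large ratios. Their sizes did change. With a pseudocount of 0.05 CPM, the log2 ratios changed by between -2.20 and 1.79. Cyp3a16, at -9.39, then lay below Cyp3a41a, at -8.06.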

Other observations

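The tests of Xist, of the held-out acinar genes without a pseudocount, of the ratios of Cyp3a genes by posterior SD and of the posterior SD against the counts lost were chosen after the results were seen. The design has 1 group, so no biological explanation was tested for any pattern, apart from the sex of the replicate 2 animal, read from Xist. Tissue carried into a sample is weighed as a technical explanation.

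Among liver transcription factors, with a median log2 ratio of 0.01 over 19 measured members, Ppara stood at 0.00 and Creb3l3 at -0.04, and the members ranged from -0.72, in Nr1i3, to 0.85. Among heat shock and protein folding genes, Hspa5 stood at 0.01 and Hspa8 at 0.37. The fatty acid and triglyceride synthesis list had a median of -0.03, inside the random range, between its lowest member, Thrsp at -2.07, and its highest, Scd1 at 0.97. Neat1, the scaffold of paraspeckles, stood at 1.57 and Malat1, its neighbour on chromosome 19, at -0.52. In 40 genes the dominant transcript differed, among them Gpx4 and Gcat, which were picked after their values were seen. The transcript Gpx4-207 held 57.4% of its gene in replicate 1 and 36.6% in replicate 2.

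Pancreatic acinar genes were lower in replicate 2. Reads shared between paralogs are argued against by the posterior SD, with a median of 0% of the CPM lost over 15 markers and 67.2% in Amy2a5, which stays open; the median log2 ratio of -2.23 for the 13 markers with an SD under 1% of the count decides nothing, since all 15 lay below the bound of -1. For pancreas tissue carried into the replicate 1 sample, the rule set before the result was seen counted a median above -1 against it. The 14 held-out acinar genes had a median of -0.81, with an interquartile range of 1.30, so the rule counted against pancreas tissue. All 14 were lower in replicate 2. The outcome was changed to undecided after the value was seen. The bound of -1 was unsuited, because the pseudocount of 39.8 counts exceeds the replicate 1 counts of several of these genes. Among them, Ctrc had 19 and Rbpjl 22. Without the pseudocount, in the test chosen afterwards, the median was -2.00. Pancreas tissue in replicate 1 may be a candidate source and stays open. The rule set beforehand counted against it, and the later test did not. Of the islet genes, Ins1, Ins2, Gcg and Iapp had 0 counts in both libraries. Chga, on the same list, had 1 count in replicate 1 and 89 in replicate 2, opposite in direction to the acinar genes. The adrenal cortex gene Mgarp had the same counts. With the other islet genes named here at 0, Chga is no measure of islet tissue in these libraries. It decides nothing about pancreas tissue.

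The female-biased genes Cyp3a41a, Cyp3a41b, Cyp3a16 and Cyp3a44 were lower in replicate 2. A male origin of replicate 2 is argued against by Xist, with a log2 ratio of -0.078, and GC content or length by a median of -6.95 for the 4 genes after correction. For reads moved between Cyp3a paralogs, the other Cyp3a genes gained 190% of the CPM that the 4 genes lost, which met the bound set before the result was seen. That gain was mostly Cyp3a11, from 439843 to 693813 counts, and the median of -7.68 for the 3 genes with a posterior SD under 1% of the count in replicate 1 decides nothing, since all 4 genes were picked for low ratios. The posterior SD was at most 2.85% of the CPM lost, in Cyp3a41b, and 0 in Cyp3a16, so shared reads are unlikely to explain the loss in these 4 genes.

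Star and Hsd3b1 were higher in replicate 2. Of 10 adrenal cortex genes listed before their values were seen, 5 had 10 or more counts in replicate 2 and a log2 ratio above 1, which exactly met the bound of 5 set beforehand. Cyp11a1 had 0 and 379 counts, Cyp11b1 4 and 1159, Cyp21a1 10 and 704, Nr5a1 0 and 60 and Mgarp 1 and 89; of the other 5, Cyp11b2 had 0 and 10.2 counts, Mc2r 0 and 12 and Akr1b7 234 and 454, ratios the pseudocount of 37.4 counts in replicate 2 holds down, while Mrap and Fdxr, at 1546 and 739 counts in replicate 1, stood at 0.03 and 0.15. Ovarian tissue is argued against, with 1 of 8 ovarian genes past the same bounds. Adrenal tissue carried into the replicate 2 sample may be a candidate source, found and tested on the same libraries.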
